A study of Mus musculus with 27 samples.

How the data were processed

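Histone marks and a histone demethylase were mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in mouse cells. Of 27 samples, 8 were immunoprecipitated for H3K27me3, 8 for H3K4me3 and 3 for UTX, and 8 were whole-cell extracts, the usual background control of the assay. The cells fell into 7 states: wild-type (WT) mouse embryonic fibroblasts (MEF), WT MEF given doxycycline (dox) to switch on the OSKM reprogramming factors, the same pair of fibroblast states with the Utx gene knocked out (Utx-KO), WT ES cells (ESC), Utx-KO ESC, and aberrant iPS clones obtained from Utx-KO MEF. Groups were taken from the sample titles and source names. Each state and mark had 1 library, except the aberrant iPS state with 2 clones.

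For each of the 19 immunoprecipitated samples the authors deposited 1 list of peaks with the chromosome, start, end, name and a score of every peak. The submitters' processing notes name CASAVA 1.8.2, Bowtie 0.12.5, MACS 1.4.1 and the mouse build mm9. The role and settings of each tool, and which control served which list, were not given in the sources used here. The deposited score behaved as MACS writes it, as -10 times the base 10 logarithm of a peak probability, and its lowest value in the lists was 50. It saturated near the top, with 16692 H3K4me3 peaks at 3100 or more, so the order of scores in that range says little about strength. Regions were ranked by score, and equal scores by width. A score reflects read depth as well as enrichment and was used to rank and filter peaks within a list. The share of peaks with a score of at least 100 is given per list as a rough sign of strength, which also depends on depth. The lists were called per sample, since each sample had its own. Read totals were not used here, so sequencing depth was unknown, and the number of peaks per list was the only sign of sensitivity. The whole-cell extracts had no peak list among the files used and were not analysed here.

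Only peaks on the numbered chromosomes, X and Y were kept, which left out 1 mitochondrial peak. Coordinates are 1-based mm9 positions. The gene table at hand was made for GRCm38, another build: 14.2% of WT ESC H3K4me3 peaks lay within 1000 bp of an end of one of its 21887 protein-coding genes against 6.32% of peaks in 20 random placements, so its positions were not used and no peak was assigned to a gene. The design fixed before the data were examined provided for this case. Regions formed by merging overlapping peaks of both lists replaced promoters, and regions are named by position. For the same reason the fixed gene lists (pluripotency, germ cell, fibroblast, epithelial, Hox, neural, mesoderm and endoderm, cell cycle inhibitor, chromatin regulator, other cell type and housekeeping genes) were not analysed here.

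In each comparison, regions carried by the first library only, by the second only and by both were counted, with an overlap of at least 1 bp. The value compared is the log2 of (regions only in the first + 1) over (regions only in the second + 1), with an exact 95% binomial (Clopper-Pearson) interval. Shares of peaks have Wilson 95% intervals, and an interval for a difference of shares combines both Wilson intervals. The latter treats the 2 lists as separate samples, although the same sites were scored in both. All intervals cover counting error over regions only. They do not cover variation between cultures, and neighbouring peaks are not independent, so no difference between libraries was tested. The 2 iPS clones are given one by one and as mean ± SD. UTX peaks were also compared with 100 random placements on the same chromosomes. The rule for naming, fixed in advance, took the 5 highest scoring regions per direction of a comparison and the 10 highest scoring peaks of each UTX list, from which the text gives a selection. Regions named outside it were chosen after their values were seen. Regions of the iPS clones were named only where both clones carried them.

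The alternatives set in advance were a score of at least 100, an overlap of at least 50% of the shorter peak or of the UTX peak, the same number of top-scoring peaks from each list, autosomes only, and each iPS clone on its own. Widening peaks by 2500 bp on each side, the 50% overlap for ESC-specific and doubly marked regions, an equal number of 4335 H3K27me3 peaks for doubly marked regions, and of 938 for H3K27me3 with dox at the doubly marked sites of WT ESC, were added after the data were seen. Runs of consecutive peaks without a counterpart were compared with 200 random orders of the same peaks within each chromosome. The overlap code was tested on simulated placements with the widths of the real peaks and against bedtools 2.31.1, and every count was recovered for 10 of 10 pairs of lists. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.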

Results

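The series asked how the H3K27 demethylase UTX shapes chromatin when fibroblasts are reprogrammed to pluripotency. H3K27me3 is the mark of Polycomb-repressed chromatin and H3K4me3 marks the promoters of active and poised genes. The data analysed were 19 peak lists, 8 for H3K27me3, 8 for H3K4me3 and 3 for UTX. They came from WT and Utx-KO MEF with and without doxycycline, which switched on the OSKM factors (Oct4, Sox2, Klf4 and c-Myc), from WT and Utx-KO ESC, and from 2 aberrant Utx-KO iPS clones. Every state other than the iPS clones had 1 library per mark, so its differences have no replicate check. UTX was mapped in WT cells only in the lists used, and the Utx-KO labels were taken as given.

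H3K27me3 differed far more between libraries than H3K4me3. The H3K27me3 lists held 4760 peaks in WT MEF, 5708 in Utx-KO MEF, 938 in WT MEF with dox, 4335 in Utx-KO MEF with dox, 5679 in WT ESC and 36231 in Utx-KO ESC. The iPS clones had 135 and 737 (mean 436 ± 426, SD, n = 2). The H3K4me3 lists ranged only from 16157 peaks in Utx-KO MEF with dox to 28232 in iPS clone 2, and their covered length ranged from 22.3 Mb in Utx-KO MEF to 55.5 Mb in iPS clone 2. Several H3K27me3 lists were weak: 2.35% of the peaks in WT MEF with dox, 17.6% of those in WT ESC and none of the 135 peaks in iPS clone 1 scored 100 or more, against 89.7% in WT MEF and 50.2% in Utx-KO ESC. These shares depend on the unknown read depth as well as on enrichment.

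**Figure D1:**
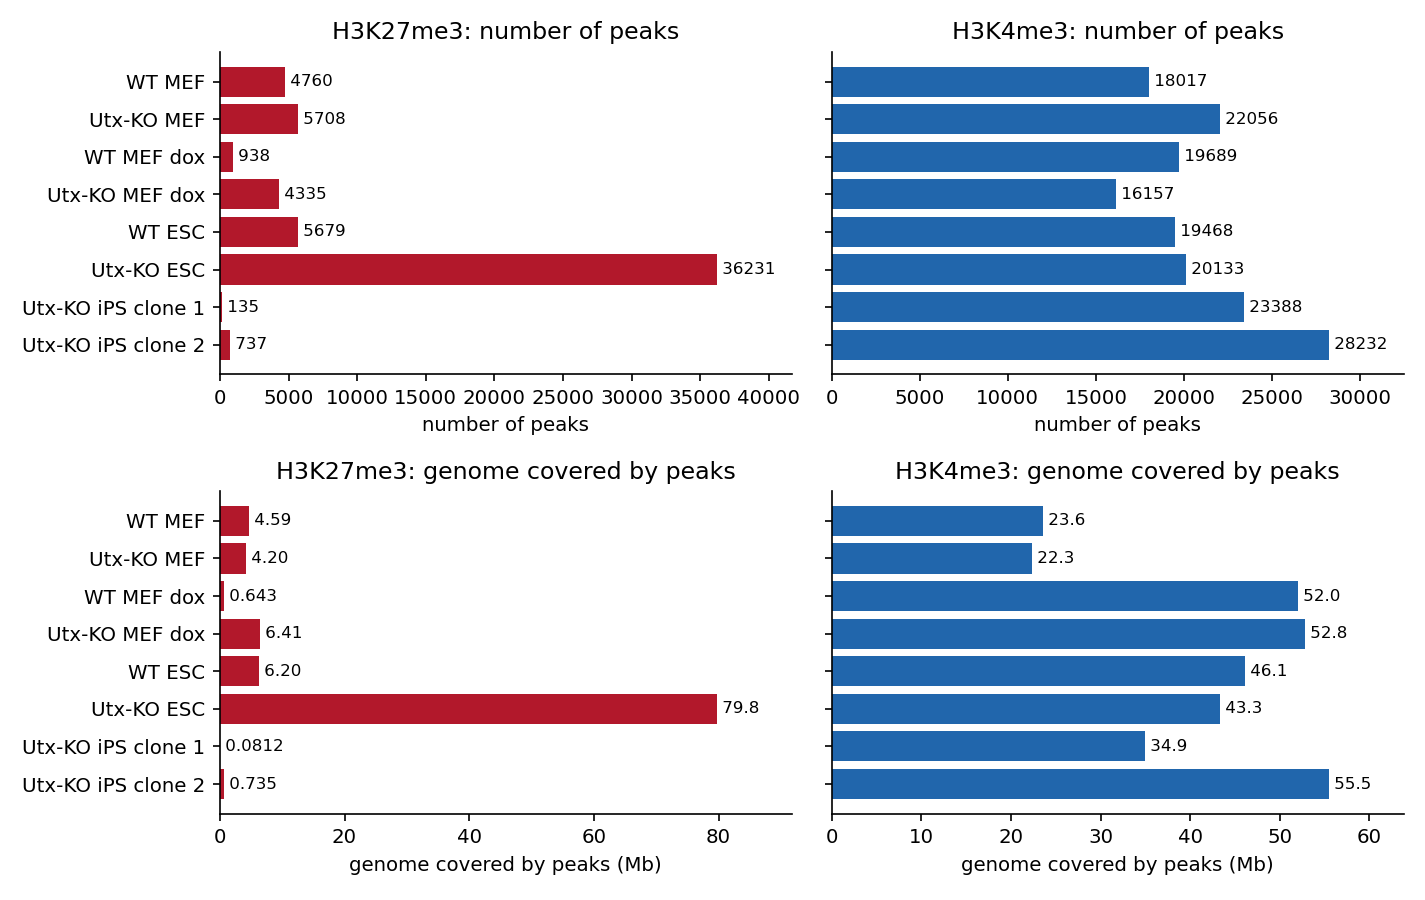
Bars show the number of peaks (top) and the Mb of genome they covered (bottom) in each H3K27me3 (red) and H3K4me3 (blue) list, 1 library per bar. The H3K27me3 list of Utx-KO ESC, with 36231 peaks over 79.8 Mb, exceeded every other H3K27me3 list, while H3K4me3 lists held 16157 to 28232 peaks.

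Doxycycline in WT fibroblasts came with broad H3K4me3 and a short H3K27me3 list. H3K4me3 peaks covered 52.0 Mb with dox and 23.6 Mb without, at median widths of 2379 and 1118 bp. There were 6991 H3K4me3 regions found only with dox, 834 found only without it and 12678 in both (log2 ratio 3.07, interval 2.96 to 3.17). For H3K27me3, 737 regions were found only with dox, 4543 only without and 196 in both (log2 ratio -2.62, interval -2.74 to -2.51). Of those 4543 regions with H3K27me3 only in untreated WT MEF, 36.8% (interval 35.5 to 38.3) carried H3K4me3 with dox and 5.44% (4.81 to 6.13) carried it without. H3K4me3 with dox was more frequent still, at 63.8% (56.8 to 70.2), in the 196 regions that had H3K27me3 in both, and 5.61% of these carried it without dox.

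Among the highest scoring H3K4me3 regions found only with dox were chromosome 4 from 128901489 to 128906280 (score 3188), chromosome 1 from 137714381 to 137719974 (3186) and chromosome 5 from 63153591 to 63158438 (3152). Each also had H3K4me3 in at least 5 other lists. H3K4me3 regions found only in untreated WT MEF included chromosome 1 from 45368502 to 45373079 (score 2143), chromosome 2 from 125859998 to 125865345 (1810) and chromosome 18 from 61204604 to 61208098 (1556). These 3 regions were present in 3 of the 8 H3K4me3 lists. The H3K27me3 regions found only without dox included chromosome 17 from 26978283 to 26984289 (score 1540), chromosome 5 from 98608834 to 98612676 (1410) and chromosome 1 from 78191141 to 78193902 (1008), each marked in 5 of the 8 H3K27me3 lists. The region with the highest score, chromosome 2 from 98506161 to 98507724 (2289), had peaks in H3K4me3 and UTX lists as well. The short H3K27me3 list with dox limits these counts, and at a score of at least 100, which left 22 of its peaks, the log2 ratio was -8.36. With equal peak numbers, which make the counts on either side nearly equal by construction where peaks pair singly, it was 0.0017.

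Loss of Utx in untreated fibroblasts left the amount of both marks similar. H3K27me3 covered 4.20 Mb in Utx-KO MEF and 4.59 Mb in WT MEF, and H3K4me3 covered 22.3 and 23.6 Mb. Regions only in Utx-KO MEF outnumbered those only in WT MEF for H3K27me3 (3883 against 3082, with 1427 in both, log2 ratio 0.33, interval 0.26 to 0.40) and for H3K4me3 (3879 against 2163, with 14334 in both, log2 ratio 0.84, interval 0.77 to 0.92). The H3K27me3 peaks were short, with median widths of 651 bp in Utx-KO MEF and 831 bp in WT MEF. A longer stretch marked in both can therefore count as several regions found in 1 list only. On chromosome 11 from 95932210 to 96073978, Utx-KO MEF had 22 such peaks and WT MEF 20, and several did not meet. The same limit holds wherever H3K27me3 regions are counted here. Chromosome X held 330 of the H3K27me3 peaks in Utx-KO MEF (5.78%) and 35 of those in WT MEF (0.735%).

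The highest scoring H3K27me3 regions of Utx-KO MEF that WT MEF lacked included chromosome 18 from 35812421 to 35814111 (score 783), chromosome 6 from 52173257 to 52175242 (654) and chromosome 15 from 102836042 to 102839108 (590). Those of WT MEF that Utx-KO MEF lacked included chromosome 13 from 55934543 to 55936906 (706) and chromosome 16 from 94094586 to 94097025 (666). For H3K4me3, chromosome 4 from 88584510 to 88588288 (score 2246) and chromosome 12 from 57798098 to 57800773 (1903) were found only in Utx-KO MEF, although each was present in 7 of the 8 lists. The H3K4me3 regions found only in WT MEF included chromosome Y from 580881 to 582474 (456) and from 621434 to 623287 (438), and Utx-KO MEF had no H3K4me3 peak on chromosome Y. On autosomes alone the H3K27me3 ratio was 0.22. With equal peak numbers, which do not test direction, the ratios were -0.038 for H3K27me3 and -0.66 (-0.74 to -0.58) for H3K4me3.

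With dox, Utx-KO and WT fibroblasts differed widely in H3K27me3. Utx-KO MEF with dox had 4063 H3K27me3 regions that WT MEF with dox lacked, against 658 in the other direction and 258 in both (log2 ratio 2.62, interval 2.51 to 2.75). H3K27me3 covered 6.41 Mb in the former and 0.643 Mb in the latter. Fewer H3K4me3 regions were found only in Utx-KO cells (920) than only in WT cells (4223), and 15166 were shared (log2 ratio -2.20, interval -2.30 to -2.10). Of the 4063 regions, 56.2% (54.6 to 57.7) carried H3K4me3 in WT MEF with dox and 41.9% (40.4 to 43.4) in Utx-KO MEF with dox.

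The H3K27me3 regions with the highest scores in this set were chromosome 6 from 52174014 to 52181269 (score 1803), chromosome 1 from 78188749 to 78197556 (1754) and chromosome 9 from 55385654 to 55394930 (1643), and the leading 5 were 5823 to 10119 bp wide. For H3K4me3, the leading regions of Utx-KO cells, chromosome 1 from 45367352 to 45374441, chromosome 2 from 125859269 to 125866319 and chromosome 18 from 61203568 to 61209235, each reached a score of 3100. They overlapped the 3 regions that stood out above as present in untreated WT MEF and missing in WT MEF with dox. The leading regions of WT cells included chromosome 17 from 25883304 to 25894139, chromosome 15 from 101191195 to 101201304 and chromosome 7 from 105304890 to 105314122, also at 3100, and the latter 2 had H3K4me3 in no other list. Of the 4223 H3K4me3 regions only in WT cells, 15.0% (13.9 to 16.1) carried H3K27me3 in Utx-KO MEF with dox. Among the 15166 shared H3K4me3 regions the share was 9.65% (9.19 to 10.1). The short WT list limits the H3K27me3 comparison, in which the ratio was 7.19 at a score of at least 100 and, near 0 by construction, 0.037 with equal peak numbers. The H3K4me3 ratio with equal peak numbers was 0.096.

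Within Utx-KO fibroblasts, dox came with wider H3K4me3 as in WT cells, and the H3K27me3 lists with and without dox overlapped only in part. H3K4me3 covered 52.8 Mb with dox and 22.3 Mb without, with 3133 regions only with dox, 962 only without and 13022 in both (log2 ratio 1.70, interval 1.60 to 1.81). H3K27me3 had 2650 regions only with dox, 3380 only without and 1474 in both (log2 ratio -0.35, interval -0.42 to -0.28), and its covered length was 6.41 Mb with dox and 4.20 Mb without. Of the H3K27me3 peaks of untreated Utx-KO MEF, 40.8% (39.5 to 42.1) met a peak with dox. Fewer, 32.0% (30.8 to 33.2), met a peak of untreated WT MEF, so low overlap was not particular to dox. Of the 1474 regions with H3K27me3 in both, 49.3% carried H3K4me3 with dox and 12.6% without.

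Leading H3K27me3 regions found only with dox were chromosome 13 from 55936068 to 55939796 (score 657) and chromosome 7 from 20108207 to 20110592 (590). Those found only without dox were led by chromosome 2 from 98506221 to 98507664 (2402) and from 98502215 to 98503317 (1174) and chromosome 9 from 35112627 to 35113284 (1161). These positions also topped the H3K4me3 regions of the same direction. They overlapped UTX peaks mapped in WT cells, as UTX was not mapped in Utx-KO cells. Peaks of every kind at the same positions leave open whether they reflect the marks. H3K4me3 regions only with dox included chromosome 11 from 63731525 to 63737923 and chromosome 13 from 56393965 to 56399151, both at a score of 3100. At a score of at least 100 the H3K27me3 ratio was -2.34. With equal peak numbers, which do not test direction, it was 0.23 (0.16 to 0.31). The H3K4me3 ratio with equal peak numbers was 4.87.

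In ES cells, H3K4me3 was similar with and without Utx, and H3K27me3 was not. The Utx-KO ESC list had 32702 H3K27me3 regions that WT ESC lacked, 1218 were found only in WT ESC and 3458 in both (log2 ratio 4.75, interval 4.66 to 4.83). H3K27me3 peaks covered 79.8 Mb in Utx-KO ESC and 6.20 Mb in WT ESC. Utx-KO ESC met 78.6% (77.5 to 79.6) of the WT ESC peaks. For H3K4me3, 2773 regions were found only in Utx-KO ESC, 2450 only in WT ESC and 16715 in both (log2 ratio 0.18, interval 0.10 to 0.26).

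H3K4me3 was present in 50.6% (48.9 to 52.2) of the 3458 shared H3K27me3 regions in Utx-KO ESC and in 12.0% (11.6 to 12.3) of the 32702 that only Utx-KO ESC had. Shared regions merge peaks of both lists, and strong peaks were shared more often. A WT ESC peak was met by 48.5% of the 3624 highest scoring Utx-KO ESC peaks and by 1.21% of the 3623 lowest. Width and score were not matched, so these shares do not separate them from an association with H3K4me3. The 32702 regions were led by chromosome X from 166429049 to 166436289 (score 2566), chromosome 2 from 31736548 to 31748035 (2469) and chromosome 2 from 160181792 to 160193424 (2388). In the opposite direction, 4 of the 5 leading H3K27me3 regions of WT ESC lay close together on chromosome 11: from 96202757 to 96205960 (score 382), 96158999 to 96164710 (205), 96152305 to 96155040 (188) and 96171147 to 96172958 (181). The H3K4me3 regions only in WT ESC were led by chromosome 14 from 49283394 to 49287249 (score 1124) and those only in Utx-KO ESC by chromosome 6 from 149513640 to 149515580 (614). At a score of at least 100, reached by 17.6% of the WT ESC and 50.2% of the Utx-KO ESC H3K27me3 peaks, the H3K27me3 ratio was 8.56 and the H3K4me3 ratio 0.95. With equal peak numbers they were 0.42 and -0.15 (-0.23 to -0.07).

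Around those 4 regions, 23 consecutive H3K27me3 peaks of WT ESC, from 96073979 to 96215747 on chromosome 11, met no H3K27me3 peak of Utx-KO ESC. The longest such run in 200 random orders of the same peaks was 9. Inside the stretch H3K27me3 covered 38.3 kb in WT ESC and 7.08 kb in Utx-KO ESC. In flanks of equal length it covered 12.1 and 8.87 kb in WT ESC but 48.4 and 81.5 kb in Utx-KO ESC. H3K4me3 covered 15.5 kb of the stretch in WT ESC and 15.8 kb in Utx-KO ESC. In fibroblasts with dox the stretch had 71.3 kb of H3K4me3 and 0.618 kb of H3K27me3 in WT cells, against 40.1 and 50.3 kb in Utx-KO cells. The short WT list with dox also had less H3K27me3 in the flanks, with 4.82 and 0 kb against 30.5 and 6.86 kb.

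**Figure D2:**
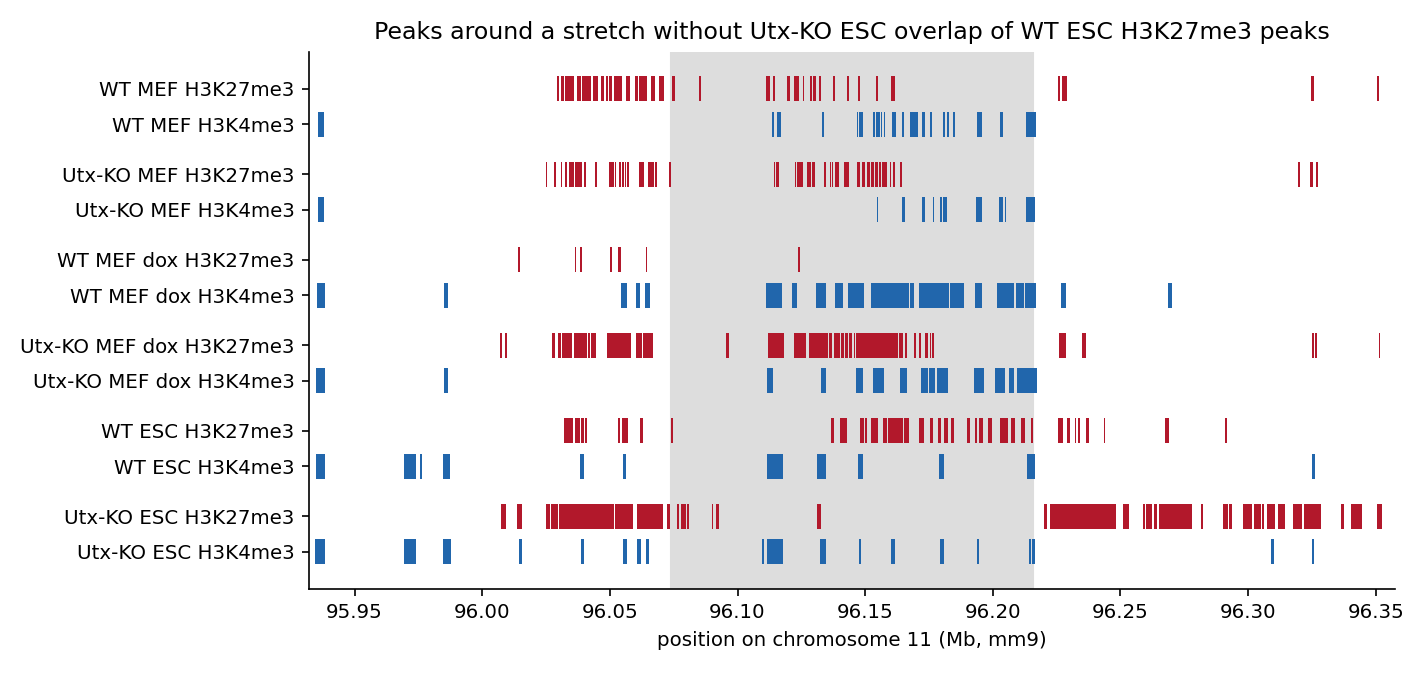
Boxes show H3K27me3 (red) and H3K4me3 (blue) peaks to scale along chromosome 11 (position in Mb, mm9) in 6 cell states. In the grey stretch from 96073979 to 96215747, WT ESC had 23 H3K27me3 peaks and Utx-KO ESC had 6, while Utx-KO ESC had dense H3K27me3 on both sides.

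The aberrant Utx-KO iPS clones had H3K4me3 at most regions marked in WT ESC and short H3K27me3 lists that shared few regions with it. H3K27me3 regions only in the clone numbered 130 in clone 1 and 720 in clone 2, while 5674 and 5663 were found only in WT ESC (mean log2 ratio -4.21 ± 1.74, SD, n = 2). No H3K27me3 peak of one clone overlapped a peak of the other. H3K4me3 regions only in the clone numbered 4393 and 9978, against 3033 and 1441 only in WT ESC (mean log2 ratio 1.66 ± 1.60, SD, n = 2). The clones shared 16309 and 17604 H3K4me3 regions with WT ESC, and 97.6% (96.6 to 98.3) and 99.6% (99.1 to 99.8) of the WT ESC sites with both marks kept an H3K4me3 peak.

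WT ESC regions without H3K27me3 in either clone were led by chromosome 2 from 31489572 to 31496459 (score 549) and from 33487592 to 33495838 (521). The H3K4me3 regions carried by both clones and not by WT ESC included chromosome X from 166412215 to 166439697 (27483 bp wide), chromosome 6 from 127097780 to 127106097 and chromosome 11 from 82743534 to 82747618. H3K4me3 regions of WT ESC that both clones lacked were led by chromosome 3 from 135211163 to 135220708 (score 1845), chromosome X from 104493445 to 104497086 (1264) and chromosome 2 from 120336361 to 120341032 (904), and each was present in only 2 of the 8 H3K4me3 lists. A failed H3K27me3 immunoprecipitation could not be separated from a true absence of the mark in these clones, and at a score of at least 100 clone 2 had 702 H3K27me3 regions of its own against 997 only in WT ESC (log2 ratio -0.51, interval -0.65 to -0.37). The spread between the clones was nearly as large as the H3K4me3 ratio itself, which was 3.04 at a score of at least 100 and -0.38 with equal peak numbers.

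UTX binding was mapped to ask which chromatin the demethylase occupies before and during reprogramming. UTX peaks numbered 372 in WT MEF, 3540 in WT MEF with dox and 5076 in WT ESC and covered 0.167, 2.08 and 3.50 Mb. In ESC, 26.1% (24.9 to 27.3) of UTX peaks lay on H3K4me3, against a mean of 2.38% in random placements. The share was 9.14% (6.61 to 12.5) in WT MEF and 7.54% (6.72 to 8.46) with dox, against random means of 1.25% and 2.49%. H3K27me3 was met by 0.217% (0.121 to 0.388) of UTX peaks in ESC, where the random mean was 0.409%. In WT MEF it was met by 9 peaks (2.42%, interval 1.28 to 4.53, random mean 0.245%) and with dox by 7 (0.198%, interval 0.096 to 0.408, random mean 0.048%). The 9 in WT MEF included the 3 strongest UTX peaks, which carried peaks of every mark, so this share rests on few peaks, some of them in doubt.

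The UTX lists had few positions in common. None of the 372 peaks in WT MEF overlapped a peak with dox, and 25 of the 3540 peaks with dox (0.706%, interval 0.479 to 1.04) met a peak in ESC. In ESC the strongest peak, at chromosome 17 from 39979794 to 39985920 (score 1737), lay outside H3K4me3 of the same cells. It overlapped peaks in 3 H3K4me3 lists and 1 H3K27me3 list of other states, so whether it reflects UTX binding is open. The peaks at chromosome 14 from 55704195 to 55705387 (546), chromosome 13 from 41240536 to 41242021 (474) and chromosome 12 from 4904344 to 4905600 (420) lay on H3K4me3. In WT MEF the 3 strongest, at chromosome 2 from 98506284 to 98507600 (320) and from 98502279 to 98503246 (254) and chromosome 9 from 35112428 to 35113287 (248), carried peaks of every mark. Peaks of every kind at the same positions leave open whether these reflect UTX binding. With dox the strongest was chromosome 18 from 6085979 to 6087125 (131). Few UTX peaks with dox were strong, as 16 of the 3540 scored 100 or more, against 1352 of the 5076 in ESC, although scores also depend on the unknown read depth.

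**Figure D3:**
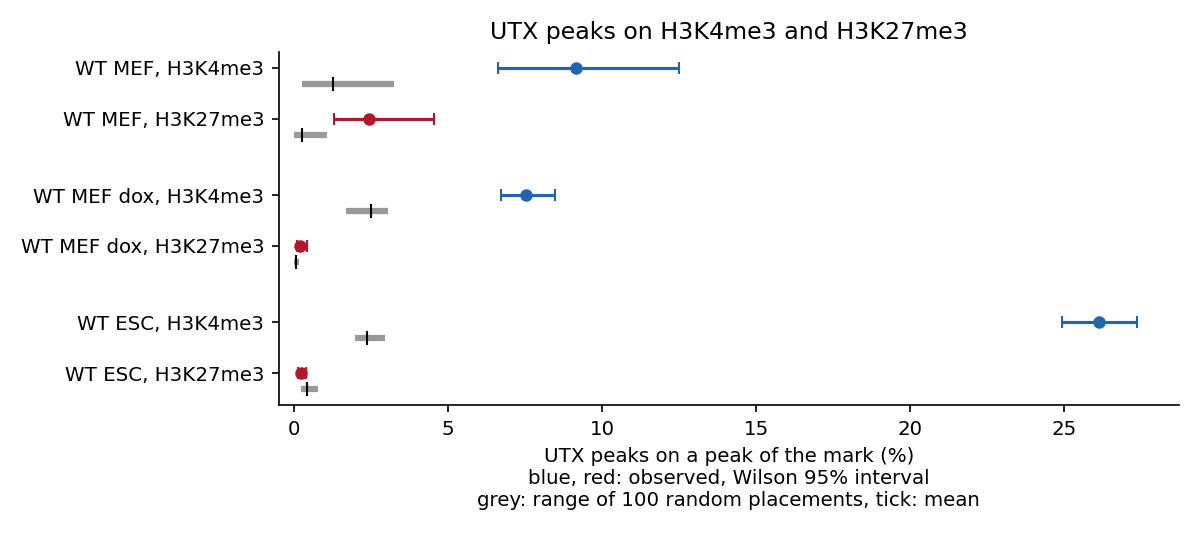
Points show the percentage of UTX peaks in each WT state that overlapped a peak of H3K4me3 (blue) or H3K27me3 (red), with Wilson 95% intervals, and grey bars show the range over 100 random placements with the mean as a tick. The share on H3K4me3 was 26.1% in ESC, 9.14% in MEF and 7.54% in MEF with dox.

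Few UTX peaks carried H3K27me3 in the cell type and treatment in which UTX was mapped, at most 2.96% in WT or Utx-KO cells. In ESC, 0.217% of UTX peaks had H3K27me3 in WT and 2.80% in Utx-KO cells, a difference of 2.58 points (interval 2.13 to 3.08). At H3K4me3 peaks without UTX the shares were 7.44% and 25.6%, a difference of 18.1 points (17.4 to 18.9), and at those with UTX they were 0.852% and 5.27%, a difference of 4.42 points (3.14 to 5.82). In fibroblasts with dox the difference at UTX peaks was 0.254 points (-0.018 to 0.553), at H3K4me3 peaks with UTX it was 4.55 points (1.66 to 7.99) and at those without UTX 9.57 points (9.11 to 10.0). Without dox it was 0.538 points (-1.94 to 3.07) at UTX peaks, which was not detectable with 372 peaks. In these untreated fibroblasts 10 of the 36 H3K4me3 peaks with UTX (27.8%, interval 15.8 to 44.0) had H3K27me3 in WT and as many in Utx-KO cells, against 1.43% and 1.45% of those without UTX. The 10 included the regions on chromosomes 2 and 9 named above, which had peaks in lists of every mark. With equal numbers of H3K27me3 peaks the differences in ESC were 0.965 points at UTX peaks, 0.697 points (-0.164 to 1.61) at H3K4me3 peaks with UTX and 6.87 points at those without. With dox they were -0.141, 0.758 (-1.41 to 3.14) and 2.98 points. At UTX peaks in ESC the difference was 0.740 points at a score of at least 100 and 9.00 points with peaks widened by 2500 bp.

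H3K4me3 was also compared at regions that distinguish ESC from fibroblasts. Of 7701 regions with H3K4me3 in WT ESC and not in WT MEF, 40.4% (39.3 to 41.5) carried it in WT MEF with dox and 28.9% (27.9 to 29.9) in Utx-KO MEF with dox, a difference of -11.5 points. The share was 10.5% in untreated Utx-KO MEF, 71.4% in Utx-KO ESC, and 62.6% and 81.6% in the iPS clones. Of 2455 regions with H3K4me3 in WT MEF and not in WT ESC, 69.0% (67.1 to 70.8) kept it in WT MEF with dox and 74.9% (73.2 to 76.6) in Utx-KO MEF with dox. The iPS clones had it at 25.1% and 45.6% of them and Utx-KO ESC at 14.5%. With equal peak numbers the difference between genotypes with dox was -3.94 points (-5.85 to -2.03) at ESC-specific regions, and the fibroblast-specific regions kept H3K4me3 in 67.0% of cases in WT and 83.7% in Utx-KO cells with dox.

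**Figure D4:**
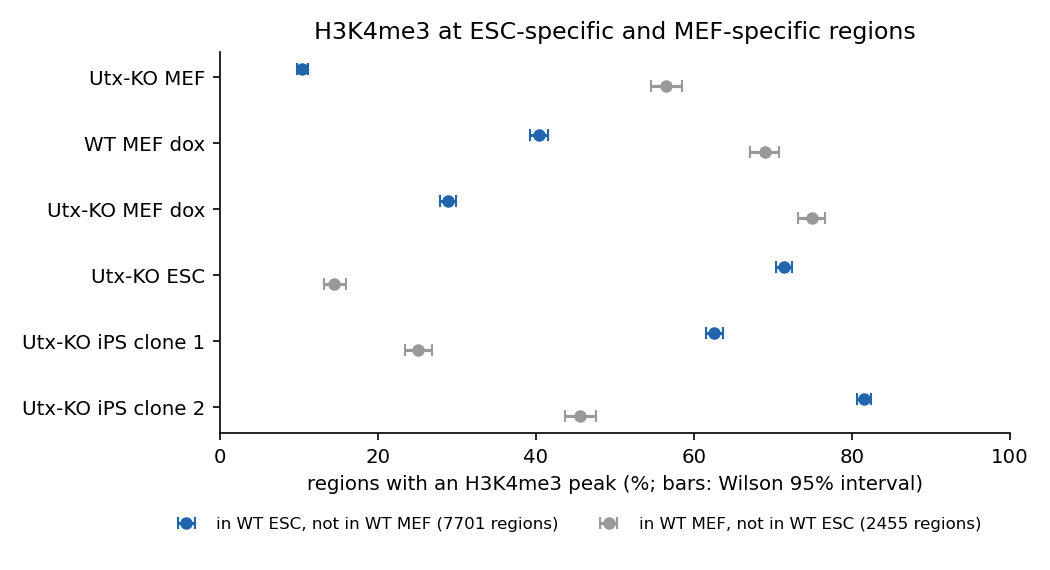
Points show the percentage of regions with an H3K4me3 peak in each state, with Wilson 95% intervals, for 7701 regions marked in WT ESC and not WT MEF (blue) and 2455 marked in WT MEF and not WT ESC (grey). Among the former, 40.4% were marked in WT MEF with dox and 28.9% in Utx-KO MEF with dox.

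Co-occurrence of both marks, the bivalent state typical of silent developmental genes in ES cells, was counted as H3K4me3 peaks that met an H3K27me3 peak of the same cells. There were 267 such peaks in WT MEF (1.48% of its H3K4me3 peaks), 184 in Utx-KO MEF (0.834%), 237 in WT MEF with dox (1.20%) and 1507 in Utx-KO MEF with dox (9.33%, interval 8.89 to 9.79). WT ESC had 1364 (7.01%, interval 6.66 to 7.37) and Utx-KO ESC 5060 (25.1%, interval 24.5 to 25.7). The iPS clones had 10 and 29. At 4335 H3K27me3 peaks per list, WT ESC had 1212 and Utx-KO ESC 2488. As a share of H3K27me3 peaks in the full lists the order was reversed, with 26.6% on H3K4me3 in WT ESC and 15.6% in Utx-KO ESC. In a ChIP-seq list of a mixed culture, both marks at 1 site can come from different cells.

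The 1364 WT ESC sites with both marks carried H3K4me3 in 47.4% of cases in WT MEF, 47.9% in Utx-KO MEF, 91.7% (90.1 to 93.1) in WT MEF with dox and 79.7% (77.5 to 81.7) in Utx-KO MEF with dox. H3K27me3 was present at 27.0% of them in WT MEF and 26.8% in Utx-KO MEF. With dox it was present at 4.40% (3.43 to 5.62) in WT cells and at 49.7% (47.1 to 52.4) in Utx-KO cells, a difference of 45.3 points (42.4 to 48.1). In Utx-KO ESC it was present at 97.6%, and in the iPS clones at 0.293% and 0.367%. At the 18104 WT ESC H3K4me3 peaks without H3K27me3, Utx-KO ESC had H3K27me3 at 18.7% (18.2 to 19.3). The WT list with dox had only 938 H3K27me3 peaks, most of them weak, and a failed immunoprecipitation could not be separated from absence of the mark. With the 938 strongest peaks of Utx-KO MEF with dox the difference was 20.7 points (18.1 to 23.2).

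**Figure D5:**
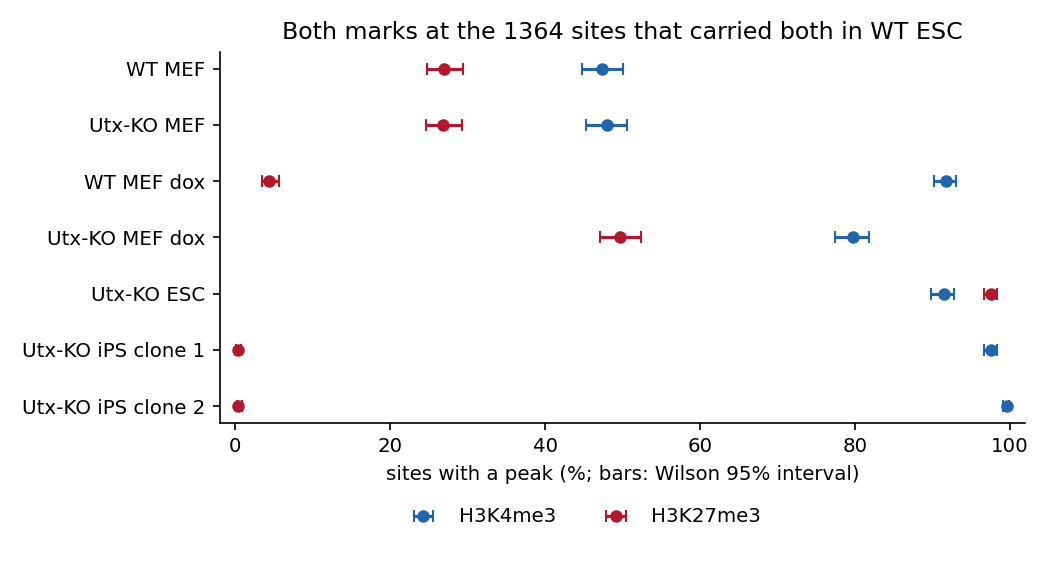
Points show the percentage of the 1364 sites with both marks in WT ESC that had an H3K4me3 (blue) or H3K27me3 (red) peak in each other state, with Wilson 95% intervals. With dox, 4.40% had H3K27me3 in WT MEF, whose list was short and weak (938 peaks), and 49.7% in Utx-KO MEF.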

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

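The tests of the difference between Utx-KO and WT ESC in this part were chosen only after the result was seen. None of the differences between cell types or genotypes given here was tested, since each rests on 1 library per state. They are given because the same change went in opposite directions in different cells by the number of peaks or by the Mb covered. With dox, the Mb covered by H3K27me3 peaks changed by -2.84 on the log2 scale in WT fibroblasts and by 0.61 in Utx-KO fibroblasts. The WT H3K27me3 list with dox, used in the values for Utx loss below as well, was short and weak. A failed immunoprecipitation could not be separated from absence of the mark. The number of H3K4me3 peaks changed with dox by 0.13 in WT and by -0.45 in Utx-KO fibroblasts. By the other measure the directions were alike: the number of H3K27me3 peaks changed with dox by -2.34 and -0.40, and the Mb covered by H3K4me3 by 1.14 and 1.24.

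For Utx loss, the Mb covered by H3K27me3 changed by -0.13 on the log2 scale in untreated MEF, by 3.32 in MEF with dox and by 3.69 in ESC, whereas the number of H3K27me3 peaks changed by 0.26, 2.21 and 2.67, all upward. The number of H3K4me3 peaks changed by 0.29 in MEF, by -0.29 in MEF with dox and by 0.048 in ESC. The Mb covered by H3K4me3 changed little, by -0.078 in MEF, 0.023 in MEF with dox and -0.091 in ESC.

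The largest of these changes, 3.69 in the Mb covered by H3K27me3 in ESC, came with 36231 peaks in Utx-KO ESC against 5679 in WT ESC. Of the 32702 Utx-KO ESC peaks without a WT ESC peak, 1.75% lay within 2500 bp of a UTX peak, 1.11 times the mean of 100 random placements (range 1.39% to 1.76%). Direct overlap with a UTX peak was found for 0.336% (random range 0.453% to 0.618%). Most of the excess therefore lay away from called UTX peaks. The 5076 UTX peaks were far fewer than the 32702, so a low share was likely whatever the cause. These values do not decide whether demethylase missing at its called peaks was the source. A local effect where UTX binds stays open. Among H3K4me3 peaks free of H3K27me3 in WT ESC, those with UTX had it less often in Utx-KO ESC (4.61% of 1280 against 19.8% of 16824, odds ratio 0.196, interval 0.150 to 0.255). Over all H3K4me3 peaks, however, the relative rise was 6.18-fold with UTX and 3.44-fold without, and 1.82-fold and 1.92-fold with equal peak numbers. The interval of the ratio of the first 2 rises, 0.948 to 3.41, treats the lists as separate samples. The same peaks were scored in both, so it does not decide whether the rises differ. A more sensitive Utx-KO ESC library and a genuine rise cannot be told apart: the 5679 strongest Utx-KO ESC peaks met 54.1% (52.8 to 55.4) of the WT ESC peaks, and without a replicate it is unknown how far lists of the same cells would match. An effect of Utx loss away from UTX peaks stays open and untested.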

How the results depend on the processing

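Widened peaks, the 50% overlap for ESC-specific and doubly marked regions, and equal numbers of H3K27me3 peaks for doubly marked regions were chosen only after the results were seen. Of 99 alternative values for 31 results, 51 stayed within a tolerance, which was the 95% interval of the reported value, 1 SD of the clones for iPS ratios and 1.5 times for counts. Some were bound to stay, namely the iPS clones taken singly and the doubly marked peaks of Utx-KO MEF with dox at equal number. Another 40 moved further, and 8 changed sign, each of these 8 with equal peak numbers. Lists of equal length have by construction about as many regions found only in one as only in the other, apart from wide peaks that span several of the other list, so these ratios do not test direction. For H3K27me3 the ratio with equal peak numbers became 0.0017 for WT MEF with dox against without, -0.038 for Utx-KO against WT MEF, 0.23 for Utx-KO MEF with dox against without, 0.037 for Utx-KO against WT MEF with dox, 0.42 in ESC and 0 for the iPS clones. For H3K4me3 the values in the same order were 2.51, -0.66, 4.87, 0.096, -0.15 and -0.38. Equal numbers also gave 20.7 points for H3K27me3 at doubly marked WT ESC sites with dox, -0.141 points at UTX peaks with dox, 0.965 points at those in ESC, -3.94 points for ESC-specific H3K4me3 and 2488 doubly marked peaks in Utx-KO ESC. At a score of at least 100 the H3K27me3 ratios were -8.36 (WT MEF with dox against without), 7.19 (Utx-KO against WT with dox), -2.34 (Utx-KO with dox against without) and 8.56 (ESC). The H3K4me3 ratios there were 3.46 (WT MEF with dox against without), 1.25 (Utx-KO against WT MEF), -2.09 (the same with dox), 0.95 (ESC) and 3.04 (iPS clones). UTX peaks numbered 53, 16 and 1352 in WT MEF, WT MEF with dox and WT ESC, with 5.66%, 18.8% and 23.8% on H3K4me3. H3K27me3 at UTX peaks in ESC differed by 0.740 points, and doubly marked peaks numbered 155 in WT MEF, 9 in WT MEF with dox, 717 in Utx-KO MEF with dox and 361 in WT ESC. With the 50% overlap the ratios were 4.61 (H3K27me3 in ESC) and 2.86 (H3K4me3, WT MEF with dox against without), UTX shares on H3K4me3 were 6.38% with dox and 21.8% in ESC, and doubly marked peaks numbered 164 in WT MEF, 115 in Utx-KO MEF, 862 in WT ESC and 5 and 17 in the iPS clones. On autosomes the H3K27me3 ratio was 0.22 for Utx-KO against WT MEF and -0.23 for Utx-KO MEF with dox against without. Widened peaks gave 9.00 points at UTX peaks in ESC. Other causes were not tested. Leaving out an iPS clone gave -5.44 to -2.97 for H3K27me3 and 0.53 to 2.79 for H3K4me3. No paired analysis was possible because no result came from a test and only the iPS state had more than 1 library. Promoter windows of 1 or 2.5 kb and gene lists were not run without mm9 gene positions. A score of at least 100 gave no H3K27me3 value for iPS clone 1 and -0.51 for clone 2, and the 3 shortest H3K27me3 lists could not be set to 4335 peaks. Unknown read depth limits every difference in peak number.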

Other observations

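Tests of chromosome X peaks in Utx-KO MEF and the comparisons of runs of peaks were chosen only after the results were seen, and the test of chromosomes 6 and 8 was set before its result. The densest H3K27me3 of these cells lay in a few clusters. In 100 kb windows, chromosome 2 from 74500001 to 74600000 ranked among the top 2 windows in WT MEF, Utx-KO MEF, Utx-KO MEF with dox, WT ESC and Utx-KO ESC, with 34.9, 31.5, 69.0, 33.5 and 89.0 kb under peaks. WT MEF with dox had 2.40 kb there. Chromosome 6 from 52100001 to 52200000 had 9.33 kb in WT MEF, 24.8 kb in Utx-KO MEF, 62.9 kb in Utx-KO MEF with dox and 0.584 kb in WT MEF with dox. Within that window Utx-KO MEF with dox also had its second widest H3K4me3 peak, of 29389 bp, from 52106004 to 52135392. Between untreated genotypes the dense windows went both ways. Chromosome 15 from 102700001 to 102800000 had 36.8 kb of H3K27me3 in WT MEF and 20.5 kb in Utx-KO MEF.

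Clusters of this kind held some of the H3K4me3 of WT fibroblasts that untreated Utx-KO fibroblasts lacked. Of all 2163 H3K4me3 regions found only in WT MEF, 6.52% (5.55 to 7.64) carried H3K27me3 in Utx-KO MEF, so most lay elsewhere. In WT MEF 5.96% (5.04 to 7.04) of them carried it, so over all these regions the share hardly differed between genotypes. There were 3 runs of 9 or more consecutive WT MEF H3K4me3 peaks without a counterpart in Utx-KO MEF, and 9 was the longest run in 200 random orders. A run of 12 peaks on chromosome 15 from 102831510 to 102866148 held 2 H3K27me3 peaks in WT MEF and 12 in Utx-KO MEF. The H3K4me3 peaks of this run scored 60.3 to 199, below the list median of 282. A run of 9 peaks nearby, from 102796282 to 102823588, held 10 and 12. On chromosome 6 from 52173021 to 52256547, 12 such peaks spanned a stretch with 24 H3K27me3 peaks in WT MEF and 35 in Utx-KO MEF. In fibroblasts with dox, the longest run of WT H3K4me3 peaks missing in Utx-KO cells was 9 peaks on chromosome 2 from 147009241 to 147875351, equal to the longest in random orders, and this stretch held 1 H3K27me3 peak in WT and 12 in Utx-KO cells.

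Chromosome X carried 330 H3K27me3 peaks in Utx-KO MEF, 54 in Utx-KO MEF with dox and 35 in WT MEF. Peaks near the calling threshold do not account for it, since X held 5.33% (interval 4.56 to 6.21) of the higher scoring 2854 peaks. A second, inactive X chromosome from a mixed or mislabelled sample, although the labels give the knock-out as Utx-/Y, and an effect of Utx loss on X cannot be told apart. Utx-KO MEF had 0 H3K4me3 peaks on chromosome Y and WT MEF had 7, but Utx-KO MEF with dox had 2, the iPS clones 3 and 6, and Utx-KO ESC 0 while only 0.836% of its H3K27me3 peaks lay on X. Only 2.73% of the X peaks met an H3K27me3 peak of WT MEF, against 33.8% of autosomal peaks. With only 35 WT MEF peaks on X, few of the 330 could meet one, so this share does not help to decide.

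In iPS clone 2, chromosomes 6 and 8 held 33.2% of the 737 H3K27me3 peaks, and in clone 1 they held 17.0% of 135, against 9.70% to 13.2% in the fibroblast and ES cell H3K27me3 lists. Their share of H3K4me3 peaks was 11.5% in clone 1 and 11.1% in clone 2, against 10.2% to 10.5% in the other H3K4me3 lists. Background from extra copies of these chromosomes could give such peaks. If so, they should meet H3K27me3 peaks of other cells less than 50% as often as peaks on other autosomes. They did so in 8.98% of 245 cases against 14.2% of 487, a ratio of 0.634 with overlapping intervals, so extra copies and true H3K27me3 cannot be told apart with so few overlaps.

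UTX peaks in ESC lay on H3K4me3 across the range of scores, from 34.1% (30.1 to 38.3) of the 508 highest scoring to 23.3% (19.8 to 27.1) of the 507 lowest scoring. A few short regions, such as chromosome 2 from 98506161 to 98507724 and chromosome 9 from 35112373 to 35113344, had strong peaks in H3K27me3, H3K4me3 and UTX lists alike and led several of the rankings in fibroblasts. Whether such shared peaks reflect the marks and UTX binding was not tested, since the whole-cell extracts were not analysed.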
